A study of Mus musculus with 6 samples.

How the data were processed

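RNA sequencing of mouse hippocampus was analysed in 6 libraries, 3 from wild type animals and 3 from Ctcf conditional knockout (cKO) animals. The strain given in the labels is C57/Bl. The series description calls the samples of each genotype biological replicates, and the labels give no Cre line, age, batch or sequencing date. RNA was extracted with a Qiagen kit and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Whether the kit kept strand information is not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart.

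Whole-number read counts per gene symbol were deposited by the authors for every library, per the file headers. The submitters' processing notes name cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3 and the mouse build mm10, without their order or settings, and the annotation version is not given in the sources used here. The same deposited table holds normalised counts, a signal obtained by dividing each library's counts by 1 size factor, per the file headers and the values. It also holds the authors' deposited log2 fold change, p-value and adjusted p-value for cKO against wild type. Library columns were matched to samples by genotype and repeat number, and 0 columns were left unmatched. The table had 24421 rows, all with a gene symbol, of which 4993 were at 0 in all libraries. It held 0 mitochondrially encoded rows.

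Total counts were 14974750, 15927042 and 19543473 in wild type replicates 1 to 3 and 16413444, 15719249 and 23220455 in cKO replicates 1 to 3. A chi-square test over genes gave a statistic of at least 10.66 per degree of freedom for every pair of libraries, so no library was a copy of another. Replicate numbers are shared by both genotypes in the labels, but nothing in the labels says that a number marks a litter or a batch, and the fit has no block. Positions came from the RefSeq annotation of GRCm38.p6, the assembly also called mm10, to which 24299 rows (99.5%) were matched by symbol or synonym. Exon length, transcript length, GC content and strand came from GENCODE M21 on the same assembly.

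The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, after its expression filter with a minimum count of 10 and TMM normalisation, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of single genes come from that test unless another is named. CPM values are counts scaled by TMM library size, given as mean ± SD over 3 libraries. The SE of a log2 fold change was taken from the fold change and the F statistic. Gene lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and adjustment over the 28 lists that had at least 3 tested genes. Camera compares a list with all other genes, while fry asks whether a list's own genes move. Before the data were examined, 30 lists were fixed. The mitochondrial list had no row in the table and the red blood cell list had 1 tested gene (Alas2, log2 fold change -0.11), so neither was tested.

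The genes named in the text follow a rule fixed before the data were examined. It takes Ctcf, the 10 largest increases and 10 largest decreases among called genes with non-overlapping groups and a mean of at least 1 CPM, and the 4 members of each list with the smallest p. It also takes Bdnf and Arc, and the 5 genes with the smallest p in each direction. Other genes are named with a statement that they were chosen after their values were seen, or because a count of members past a threshold includes them. Some genes that the rule takes are not reported here.

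Adjacent called genes were counted along each chromosome and compared with 10000 random shuffles of the calls and their directions over gene positions, and with 2000 shuffles for each alternative. The test was checked on 10 simulated data sets of cKO against wild type, with 200 genes of at least 5 CPM changed in each. The edgeR test ran on 14777 to 14810 simulated genes and recovered 37.6% of genes changed 1.5-fold, 85.8% of those changed 2-fold, 99.2% of those changed 4-fold and 99.6% of those changed 8-fold. False calls made up 6.93% of all simulated calls, slightly above the nominal 5%. Simulated genes varied independently of each other, so these rates do not cover differences between libraries that many genes share, such as tissue content.

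Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile scaling, 2 other filters, the replicate number as a block, other thresholds, and each library left out in turn. For the lists they were camera with an estimated correlation and fry. Camera with an estimated correlation also takes its degrees of freedom from the few libraries rather than the many genes, so it has less power. For length and neighbours they were other gene lengths and pairs within 100 kb. Alternatives added after seeing the data left out wild type replicate 2 and cKO replicate 1 together, or used the level of striatal or of choroid plexus markers as a covariate.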

Results

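Gene expression was measured by RNA sequencing in hippocampus from 3 wild type and 3 Ctcf cKO mice, at 14974750 to 23220455 counted reads per library. The design asks how loss of CTCF, a zinc finger protein that binds DNA and acts at chromatin loops and insulators, alters hippocampal transcription. After filtering, 14916 genes were tested. The Y-linked genes Ddx3y and Eif2s3y had at least 388 counts in every library and Xist at most 11, so all 6 libraries showed the same sex-marker pattern.

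Ctcf itself (chromosome 8, 105636474 to 105682922, GRCm38) fell from 66.6 ± 3.23 CPM in wild type to 31.5 ± 6.42 CPM in cKO (SD, n = 3 each). Its log2 fold change was -1.08 (SE 0.15, adjusted p = 0.0264), and every cKO library lay below every wild type library. The lowest level, 24.1 CPM, was in cKO replicate 1, and the other cKO libraries had 34.5 and 35.8 CPM. The log2 fold change stayed negative without any 1 library, but the adjusted p was 0.0604 without wild type replicate 1, 0.101 without wild type replicate 3 and 0.124 without cKO replicate 2. It was 0.453 with the striatal marker level as a covariate (log2 fold change -0.79) and 0.15 with the choroid plexus level (-0.85).

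Loss of Ctcf was accompanied by increases in more genes than decreases, with 156 genes higher and 69 lower in cKO. Robo3, an axon guidance receptor, rose from 30.5 ± 11.2 to 247.8 ± 44.4 CPM (log2 fold change 3.03, SE 0.27). Cyp11a1, which carries out the first step of steroid hormone synthesis, rose from 3.42 ± 0.79 to 26.5 ± 7.46 CPM. Asl, an enzyme of the urea cycle, rose from 16.8 ± 2.90 to 74.1 ± 9.40 CPM. Pdyn, the precursor of dynorphin peptides, fell from 46.1 ± 25.0 to 6.90 ± 0.71 CPM.

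The smallest p belonged to Fchsd1, an F-BAR and SH3 domain protein gene, which rose from 9.52 ± 0.31 to 47.3 ± 3.15 CPM (log2 fold change 2.31, SE 0.09, adjusted p = 0.000266). Fchsd1 lies on chromosome 18 (37957431 to 37969814) and overlaps Rell2, so reads of their shared part are uncertain. Stx2, a membrane fusion protein of the syntaxin family, rose by 1.41 on the log2 scale, and Ism1, which encodes a secreted protein, by 1.72. Other large increases were in Nmbr, the neuromedin B receptor (log2 fold change 2.46), and Rxfp1, the relaxin receptor (2.64). Mnd1, a meiotic recombination gene, rose by 4.76 from 0.15 CPM, and its pseudogene Mnd1-ps on chromosome 14 rose by 4.02. Reads of that pair could be assigned to either copy, so both values are uncertain. The non-coding or unnamed genes E030013I19Rik and 4930579G24Rik rose by 3.49 and 2.56.

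Among the decreases, Wfs1, an endoplasmic reticulum protein and marker of CA1 neurons, fell from 109.1 ± 13.7 to 48.8 ± 1.43 CPM (log2 fold change -1.16, adjusted p = 0.00775). Gm996 fell from 150.8 ± 5.17 to 60.3 ± 7.80 CPM. Nsmce4a, a subunit of the SMC5/6 complex, Adprhl2, an ADP-ribose hydrolase, and Def8 had log2 fold changes of -0.74, -0.86 and -0.63. The receptor genes Adra2c (an adrenoceptor), Htr1d (a serotonin receptor) and Cd4 had log2 fold changes of -2.18, -2.44 and -3.90. Fst, the activin antagonist follistatin, fell from 2.83 ± 1.08 to 0.20 ± 0.19 CPM. Lrrc10b, Mafa, Tmprss6 and Pcdhb13 completed the 10 largest decreases, with log2 fold changes of -1.34, -1.77, -2.08 and -1.33. In wild type, Pdyn, Adra2c and Cd4 were highest in replicate 2, at 74.8, 53.7 and 34.2 CPM, as were Htr1d, Fst, Lrrc10b, Mafa and Wfs1, and striatal marker genes were highest in the same library.

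**Figure D1:**
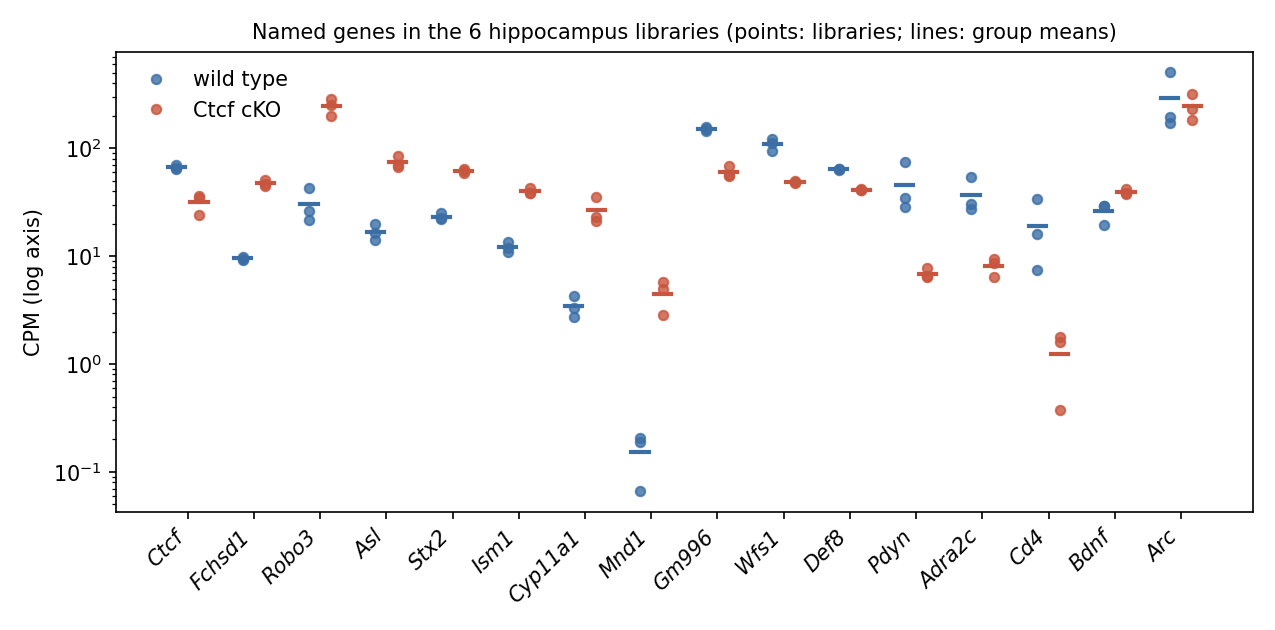
CPM (log axis) of 16 named genes in the 3 wild type and 3 Ctcf cKO libraries; points are libraries and horizontal lines are group means. Ctcf averaged 66.6 CPM in wild type and 31.5 CPM in cKO, and Robo3 averaged 30.5 and 247.8 CPM, while the groups overlapped for Arc.

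In all, 225 genes passed the test, and 68 of them had an absolute log2 fold change of at least 1 (47 higher, 21 lower). All 225 had non-overlapping groups, as did 27% of all genes tested, against 10% by chance. The authors' deposited table listed 789 genes with adjusted p below the same threshold (468 higher, 321 lower), and these included all 225 in the same direction. The count fell when any 1 library was left out, by unequal amounts. It was 35, 147 and 12 without wild type replicates 1, 2 and 3, and 13, 14 and 79 without cKO replicates 1, 2 and 3. It was 876 with DESeq2, of which 59% were higher in cKO against 69.3% with edgeR. With the striatal marker level, which itself separated the genotypes, as a covariate, edgeR called 0 genes, with 1613 at an unadjusted p below 0.05, and without wild type replicate 2 and cKO replicate 1 it called 111.

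Clustered protocadherins, cell adhesion proteins whose isoforms are each expressed from their own promoter, had negative log2 fold changes in 47 of 53 tested members, and 5 fell over all genes. All 21 tested Pcdh beta genes had negative log2 fold changes, with a median of -0.77. In this group 3 genes fell, Pcdhb13 (log2 fold change -1.33), Pcdhb17 (-0.997) and Pcdhb7 (-1.11), and 14 fell when adjusted over the list alone. Of 22 Pcdh gamma genes, 17 had negative log2 fold changes, Pcdhga9 (-0.90) and Pcdhga2 (-1.10) fell, and adjusted over the list alone 14 were lower and Pcdhgc4 (0.45) was higher. Of 10 Pcdh alpha genes 9 had negative log2 fold changes, none passed over all genes, and 5 were lower adjusted over the list alone, among them Pcdha9 (-0.97) and Pcdha10 (-0.95). Isoforms share downstream exons within the alpha and gamma clusters, so their reads could in part be assigned to several genes. DESeq2 called 21 clustered protocadherins lower and none higher. The 5 called by edgeR went to 0 without wild type replicate 1, wild type replicate 3 or any 1 cKO library, and to 2 without wild type replicate 2.

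The camera test called all 3 clusters lower, with adjusted p of 2.36e-11 for beta, 3.7e-07 for gamma and 0.00356 for alpha. With an estimated correlation (0.183 for beta, 0.0465 for gamma and 0.00908 for alpha) the adjusted p by camera was 0.27 for each. For alpha the estimate lay below the preset 0.01, so a higher correlation cannot account for the loss of its call. The alpha call was also lost with the striatal covariate (adjusted p = 0.0949). With fry the adjusted p was 0.0143 for beta, 0.0109 for gamma and 0.0109 for alpha. The fry calls were lost for all 3 clusters without cKO replicate 2 (adjusted p = 0.0646 for each) and with the striatal (0.282 to 0.388) or choroid plexus covariate (0.107 to 0.175). For beta the fry call was also lost without wild type replicate 2 (0.0508) or 3 (0.0556). Without wild type replicate 2 and cKO replicate 1 no single clustered protocadherin was called, while the camera adjusted p was 1.13e-11, 5.27e-06 and 0.0119. In those 4 libraries it was 0.495, 0.495 and 0.606 with an estimated correlation, and the fry adjusted p was 0.157, 0.122 and 0.122. The 8 striatal markers were also lower in cKO, adjusted over the list alone.

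**Figure D2:**
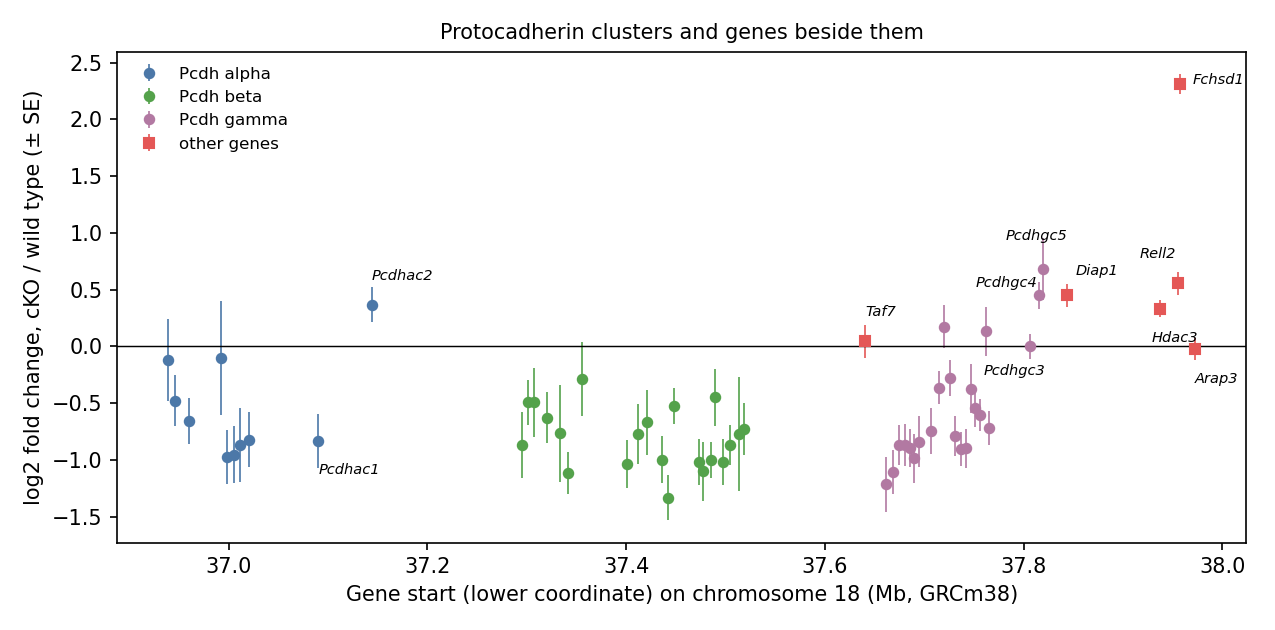
Log2 fold change (cKO over wild type, bars ± SE, 3 libraries per group) of each tested gene against its start on chromosome 18 in Mb (GRCm38), for the Pcdh alpha, beta and gamma clusters and neighbouring genes. All 21 Pcdh beta genes lie below 0, and Fchsd1 beyond the gamma cluster lies at 2.31.

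Non-clustered protocadherins had 10 of 11 positive log2 fold changes (median 0.27). None passed over all genes, and Pcdh8 (1.22) was higher adjusted over the list alone. Camera gave an adjusted p of 0.0131, or adjusted p = 0.321 with an estimated correlation and 0.0949 with the striatal covariate.

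Genes of excitatory synapses and glutamatergic neurons had positive log2 fold changes in 26 of 28 cases (median 0.22). None passed over all genes. Homer2 (0.78), a postsynaptic scaffold protein, and Shank1 (0.39), a scaffold of the postsynaptic density, were higher adjusted over the list alone. The list rose by camera (adjusted p = 0.000515), but adjusted p = 0.529 with an estimated correlation and 0.185 with the striatal covariate. The groups overlapped in its mean level, with cKO replicate 3 (-0.051 on the log2 scale from the mean of the 6 libraries) below wild type replicate 3 (-0.029). Voltage-gated ion channel genes also rose by camera (adjusted p = 0.00138, and adjusted p = 0.33 with an estimated correlation or 0.333 with the striatal covariate). There, Cacna1d, an L-type calcium channel gene, rose by 0.46, and adjusted over the list alone 6 genes were higher, including Cacna1a (0.50) and Cacna2d1 (0.54), and 1 was lower, Scn4b (-1.61). In cohesin and CTCF-associated factors, Stag1, a cohesin subunit, rose by 0.71 and was the 1 gene of 17 that passed, also adjusted over the list alone. That list's adjusted p was 0.00676, or adjusted p = 0.461 with an estimated correlation and 0.0525 with the striatal covariate. The mean level of oligodendrocyte markers was lowest in cKO replicate 1 (-0.38 on the log2 scale from the mean of the 6 libraries), and wild type replicate 1 (-0.07) lay below cKO replicates 2 (-0.02) and 3 (-0.05).

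Immediate early and activity-regulated genes did not pass as a list (adjusted p = 0.172), and none of 37 passed singly. The list was higher by camera without wild type replicate 2 (adjusted p = 0.000454), without cKO replicate 3 (0.0447), without wild type replicate 2 and cKO replicate 1 (0.00353) and with the striatal covariate (0.00443). With an estimated correlation none of these held (adjusted p = 0.558, 0.753, 0.606 and 0.699). Adjusted over the list alone, Ptgs2 (0.91), Nr4a2 (0.44) and Npas4 (0.74) were higher. Bdnf, a neurotrophin, had 26.0 ± 5.74 CPM in wild type and 39.3 ± 2.20 CPM in cKO (log2 fold change 0.59, adjusted p = 0.119), while the authors' deposited table gave Bdnf an adjusted p of 0.0305. Arc, a synaptic plasticity gene, had 291 ± 185.9 and 244 ± 68.6 CPM (log2 fold change -0.25, adjusted p = 0.773), with 505.3 CPM in wild type replicate 2.

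The 8 striatal markers, among them Drd1, Drd2, Adora2a, Ppp1r1b and Penk, were all lower adjusted over the list alone, and edgeR called none over all genes, while DESeq2 called all 8. Without the low-count filter edgeR called 4, and without wild type replicate 2 and cKO replicate 1 it called 2. Penk, the precursor of enkephalin peptides, had 131.1, 705.8 and 280.4 CPM in wild type replicates 1 to 3 and 12.3, 79.4 and 40.2 CPM in cKO replicates 1 to 3. The list of 21 neighbouring region genes, which holds these 8, had 11 negative and 10 positive log2 fold changes (median -0.10, mean -1.06), and the 8 were its only members that passed adjusted over the list alone. Camera called that list lower (adjusted p = 0.0301), with adjusted p = 0.33 with an estimated correlation, 0.161 without wild type replicate 3 and 0.173 with the striatal covariate. That covariate is the mean level of the same 8 members, so it takes out their shift by construction and the last value decides nothing. Choroid plexus and ependyma markers had 18 of 18 negative log2 fold changes (median -1.17), none passed over all genes or adjusted over the list alone, and Ttr, their transthyretin gene, had 557.5 CPM in cKO replicate 1 against 3067 to 11669 CPM in the other libraries. Camera called that list lower (adjusted p = 1.31e-05, and adjusted p = 0.668 with an estimated correlation). With the striatal covariate it was higher (adjusted p = 0.00374, and adjusted p = 0.702 with an estimated correlation).

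**Figure D3:**
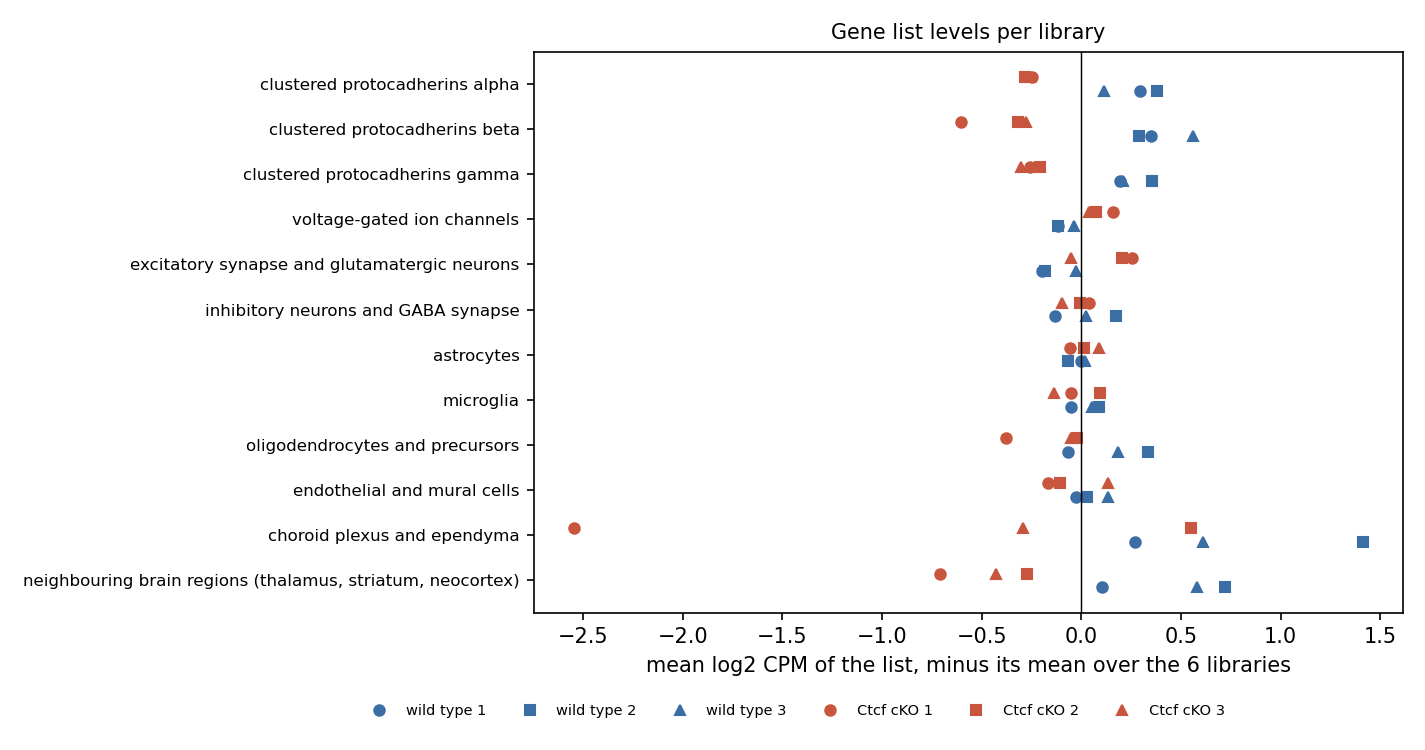
Mean log2 CPM of 12 gene lists in each library, minus the list's mean over the 6 libraries; colours are groups and symbols are replicates. All cKO libraries lie below all wild type libraries for the 3 clustered protocadherin lists and for the neighbouring brain regions list, and above them for voltage-gated ion channels. The choroid plexus level of cKO replicate 1 stands apart from the rest.

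Oligodendrocyte genes had 18 of 18 negative log2 fold changes (median -0.32), among them Mbp (-0.43), Mag (-0.40) and Cnp (-0.41), and none passed over all genes or adjusted over the list alone. Camera called the list lower (adjusted p = 1.31e-05, and adjusted p = 0.59 with an estimated correlation). The list was higher with the striatal covariate (adjusted p = 0.0175, and adjusted p = 0.699 with an estimated correlation) and did not pass with the choroid plexus covariate (0.058). Lists of astrocyte (adjusted p = 0.755), microglia (0.226), endothelial and mural cell (0.172) and meningeal genes (0.332) did not pass, and no member of these passed singly or adjusted over the list alone. Gfap and Tyrobp, for example, had log2 fold changes of 0.19 and 0.27. The microglia list was lower without cKO replicate 2 (adjusted p = 0.0298), and the endothelial and mural list without cKO replicate 3 (0.0181), but adjusted p = 0.651 and 0.432 with an estimated correlation. Disease-associated microglia genes did not pass by camera (adjusted p = 0.0956) and were lower by fry (0.0476), a call lost without any 1 library (0.0556 to 0.217) and with a mean CPM filter (0.0517), and Lpl (-0.93) was lower adjusted over the list alone.

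Markers of inhibitory neurons (adjusted p = 0.963), of newborn neurons and proliferation (0.0956) and learning and memory regulators (0.633) had no called member, over all genes or adjusted over the list alone. The newborn neuron list was lower without wild type replicate 1 (adjusted p = 0.0251) or cKO replicate 2 (0.0298), but adjusted p = 0.61 and 0.651 with an estimated correlation. Markers of the hippocampal fields did not move one way as a list (adjusted p = 0.755), with Wfs1 lower and Rxfp1 higher, as also when adjusted over the list alone. With the striatal covariate camera called that list lower (adjusted p = 0.0454, and adjusted p = 0.699 with an estimated correlation). Among neuropeptides and trophic factors Pdyn fell, and adjusted over the list alone Pdyn, Tac1 and Penk were lower and Bdnf higher (list adjusted p = 0.378). Bdnf did not pass over all genes (adjusted p = 0.119) or when adjusted over the immediate early list alone. Tac1 and Penk are among the 8 striatal markers, and Pdyn was highest in the same wild type library as those markers.

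In the imprinted list, the non-coding RNAs Rian (0.59) and Mirg (0.73) of the Dlk1-Meg3 locus and Ube3a (0.60), a ubiquitin ligase, rose, and no member fell. Adjusted over the list alone 6 were higher, including Kcnk9 (0.99) and Meg3 (0.52), and 2 were lower, Sgce (-0.49) and Nnat (-0.55). The list as a whole did not pass (adjusted p = 0.172), and was higher without wild type replicate 1 (0.0295, but adjusted p = 0.667 with an estimated correlation). Ccng1, a p53 target, rose by 0.76, and adjusted over the list alone Rprm (-2.05) was lower, with a list adjusted p of 0.459. Heat shock and unfolded protein genes had no called member, 1 higher (Hmox1) and 3 lower (Bag3, Dnajb1 and Hspa1a) adjusted over the list alone, and a list adjusted p of 0.154, or 0.0389 without wild type replicate 3 (adjusted p = 0.345 with an estimated correlation) and 0.0392 with the choroid plexus covariate (adjusted p = 0.74 with an estimated correlation). Interferon response (0.24) and MHC class I genes (0.459) did not pass as lists, and no member was called, also adjusted over the list alone. Without wild type replicate 1 the interferon list was lower (adjusted p = 0.0101, but adjusted p = 0.361 with an estimated correlation).

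Of 66 ribosomal protein genes Rplp0 (-0.46) fell, also adjusted over the list alone. Camera gave adjusted p = 0.0478, and adjusted p = 0.696 with an estimated correlation. It was 0.543 without wild type replicate 1, 0.0769 without cKO replicate 2 and 0.23 without cKO replicate 3. The 4 tested Y-linked genes, with Kdm5d at 0.28 and Uty at 0.36, had a list adjusted p of 0.0399, and adjusted p = 0.465 with an estimated correlation, with none called over all genes or adjusted over the list alone. Without wild type replicate 1, wild type replicate 2 or cKO replicate 3 it was 0.103, 0.0653 and 0.135, and with the striatal covariate 0.0949. In total 12 of 28 lists passed camera. None passed with an estimated correlation, a setting with less power here, so these losses cannot be put down to gene correlation alone. Fry called 4 in one direction. For change in either direction fry called 10, among them the hippocampal field (adjusted p = 0.00133), p53 (0.00202), imprinted (0.00202) and heat shock (0.00266) lists, which camera did not call. The mean and camera were positive and the median negative for learning and memory regulators, and fry differed in sign from camera for inhibitory neurons and hippocampal fields.

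The Spearman correlation across 14877 genes between log2 fold change and genomic span was 0.14, and 0.079 without wild type replicate 1. With GC content it was -0.239. Genes are not independent replicates, and other splits of the 6 libraries gave absolute values of 0.014 to 0.177 for span. With genes divided into 5 equal groups by span, 45 of 54 called genes in the longest group (median 137 kb) and 50 of 58 in the next (49 kb) were higher in cKO, against 16 of 34 in the middle group (24.1 kb), 21 of 33 in the group below it (12.1 kb) and 23 of 45 in the shortest (4.23 kb).

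Called genes lay next to each other on chromosomes, in the order of the tested genes, more often than under shuffling. Of 17 adjacent pairs of called genes, 15 changed in the same direction, against a mean of 1.93 and a maximum of 8 such pairs in 10000 shuffles (one-sided permutation p = 1e-04, the smallest that the shuffles can give). On chromosome 3, Etfdh (log2 fold change 1.06), 4930579G24Rik (2.56), Rxfp1 (2.64) and Tmem144 (1.39) rose in a run between 79603788 and 79852787. Nmbr and 1700016L04Rik rose side by side on chromosome 10, as did Robo3 and Msantd2 (0.60) on chromosome 9, Obsl1 (0.86) and Inha (0.88) on chromosome 1, and Tmc3 (0.90) and Stard5 (1.64) on chromosome 7. The level of 1700016L04Rik was near the floor, at 0.02 CPM in wild type and 1.01 CPM in cKO. The partners Oxr1 (-0.49) and Angpt1 (1.62), and Rerg (-1.05) and Ptpro (0.81), changed in opposite directions. Pair members outside the fixed naming rule were chosen after their values were seen. No adjacent pair in one direction was left without wild type replicate 3, cKO replicate 1 or cKO replicate 2, where 12 to 14 genes were called, or with the choroid plexus covariate, where 12 were called, and 1, 9 and 2 were left without wild type replicate 1, wild type replicate 2 and cKO replicate 3.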

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

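Alternatives that left out wild type replicate 2 and cKO replicate 1 together, or used a marker level as covariate, were chosen after seeing the data. The count of 225 called genes was between 185 and 276 under the other scalings and filters, limma-voom and the replicate block, and 876 with DESeq2 (59% higher), 691 at an adjusted p below 0.1, 20 below 0.01 (90% higher) and 68 with an absolute log2 fold change of at least 1. With 1 library left out, 12 to 147 genes were called and 66% to 91.7% were higher, with Ctcf at -1.19 to -0.92 (adjusted p 0.0272 to 0.124); fewer samples lower the power. Without wild type replicate 2 and cKO replicate 1 the count was 111, of which 79 were among the 225. With the striatal level as covariate 0 genes were called (1613 at an unadjusted p below 0.05), and Ctcf was at -0.79 (adjusted p = 0.453). With the choroid plexus level there were 12 (100% higher), Ctcf was at -0.85 (adjusted p = 0.15) and 0 adjacent pairs were left. The striatal level separates the genotypes, and with it all 225 genes kept their sign while the SE of Ctcf was 0.263 against 0.148. With replicate numbers as a block 185 genes were called, 125 of them shared, and 57.8% were higher; same-numbered libraries deviated with correlations of 0.219, 0.425 and 0.079, not all over 0.1, so the numbers were not taken as pairs. Wild type replicates 1 and 2 correlated best with their own number and replicate 3 with cKO replicate 1 (0.08), a hint from the data, not the design. The block called all 8 striatal markers and 3 clustered protocadherins, and ended the fry calls of Pcdh alpha (0.0942) and disease-associated microglia (0.158). It also ended the camera call of ribosomal protein genes (0.0858), and added fry calls of the neighbouring region and sex chromosome lists (0.0181 each). Of 28 lists, 12 passed, against 0 with an estimated correlation (a setting with less power), 4 with fry and 7 with the striatal covariate. That covariate reversed the hippocampal field (-0.44), oligodendrocyte (0.15) and choroid plexus (1) medians, and the cause was not tested. The length correlation of 0.14 was 0.233 with exon length, 0.226 with transcript length, 0.066 with DESeq2 and with no filter, 0.219 with the striatal and 0.207 with the choroid covariate; the cause was not tested. Adjacent pairs in one direction numbered 70 with DESeq2, 12 with limma-voom, and 8 with upper-quartile scaling and with the block. They numbered 13 with DESeq2 size factors, 15 with no filter and 19 with a mean CPM filter. With 1 library left out there were 0 to 9, and all 15 were left when protocadherins were removed, which takes out no pair and so decides nothing. No named called gene reversed in 16 settings, and 372 of 608 values of the 39 named called genes, leaving out Ctcf itself, stayed past the threshold. Real groups gave 225 called genes and the highest of the other splits gave 1; of 10 splits, 1 gave as many, too few for a share under 0.05. Genes changed by 1.5-fold were recovered in 37.6% of simulated cases, so changes of that size are often missed at this depth with 3 libraries per group.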

Other observations

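The tests of striatal tissue and of adjacent pairs without the 2 outlying libraries were chosen only after the result was seen, as were the genes named in the next paragraph outside the fixed rule. Those 2 libraries, wild type replicate 2 and cKO replicate 1, were the ends of the first principal component of log2 CPM (53.8% of the variance). Along it came wild type replicates 2, 3 and 1, then cKO replicates 2, 3 and 1. The mean level of the striatal markers fell in the same order, so that level and genotype cannot be separated along this axis.

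Of the 48 tested clustered protocadherins other than the C-type isoforms, 46 had negative log2 fold changes, with a median of -0.78, and Pcdhgb4 (0.17) and Pcdhgb8 (0.13) were positive. The C-type genes went both ways, with log2 fold changes of -0.83 for Pcdhac1 and 0.37, 0.0032, 0.45 and 0.68 for Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, and none passed over all genes. Beyond the gamma cluster, Diap1 (0.45, SE 0.10, adjusted p = 0.0833) and Hdac3 (0.33, SE 0.08, adjusted p = 0.0799) did not pass, Rell2 (0.56) and Fchsd1 (2.31) rose, and Arap3, the next gene, had a log2 fold change of -0.03. Taf7, which lies between the beta and gamma clusters, had a log2 fold change of 0.05. The difference between C-type and other isoforms was not tested.

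The 8 striatal markers were lower in cKO with a median log2 fold change of -2.79. They ordered the 3 wild type libraries identically, with a 4.79-fold range between the highest and lowest library in their mean, so differing amounts of striatal tissue in the dissections may account for their decrease. A single wild type library did not carry the difference, since the median was -1.99 without wild type replicate 2. Of the 69 called decreases, 30.4% (21 genes) had the same order of wild type libraries as these markers, against 16.7% by chance. This share cannot decide how many decreases followed the markers. The test disfavours genes that vary widely within wild type, and it called none of the 8 markers. Among the 10 largest decreases named above, Cd4, Fst, Pdyn, Htr1d, Adra2c, Mafa and Lrrc10b had that order, and Tmprss6, Pcdhb13 and Gm996 did not. Every cKO library lay below every wild type library in the mean of the markers, so a loss of their expression in cKO stays open and was not tested.

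The excess of adjacent called pairs in one direction was not explained by chance placement (permutation p = 1e-04, the smallest possible). Reads shared by overlapping genes would need most pairs to overlap or to be copies, and 6.67% did. That count does not cover pairs that lie close without overlap. Among them were Etfdh and 4930579G24Rik (0.312 kb apart), 1700016L04Rik and Nmbr (0.337 kb), Obsl1 and Inha (0.591 kb), and H2afz and Dnajb14 (0.753 kb). Adjacency was counted among tested genes only, so partners could also lie far apart, as Mex3b and Tmc3 did (713 kb). Without wild type replicate 2 and cKO replicate 1, 6 pairs were left, all in one direction (permutation p = 1e-04, the smallest possible), against a mean of 0.46 in shuffles, so the pattern did not rest on these 2 libraries alone. With 12 to 14 calls, as without wild type replicate 3, cKO replicate 1 or cKO replicate 2 or with the choroid plexus level as covariate, no pair was left. Shared regulation of neighbours in cKO stays open and was not tested, because CTCF binding was not analysed here.

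DNA from a donor strain around the targeted allele could raise the share of called genes near Ctcf. Within 20 Mb of Ctcf 4 of 317 tested genes were called, Def8, Chd9, Acta1 and Bean1, against 219 of 14559 elsewhere (odds ratio 0.837, 95% interval 0.225 to 2.2, Fisher's exact test, two-sided, p = 1). The upper bound lay above 2, so a modest excess cannot be told apart from none with 4 called genes.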
